A study of Mus musculus with 12 samples.

How the data were processed

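The series holds 12 arrays of a mouse Illumina expression BeadChip, 1 per RNA sample, of whole NOD mouse embryos at embryonic day 10.5. The groups were taken from the labels: 4 control pools, each made of RNA from 4 embryos of normal pregnancies, 4 diabetic pools, each made of RNA from 4 embryos of diabetic pregnancies, and 4 individual embryos with a neural tube defect (NTD embryos) from diabetic pregnancies. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase and purified on a column, equal amounts from embryos of separate pregnancies were pooled, and 200 ng per sample was amplified and labelled with a biotin kit. Dams were counted as diabetic above 250 mg/dL glucose, and the protocol names an injection of 5 units of gonadotropin for diabetic dams. The labels do not say whether control dams received it too; if they did not, the groups differ in this treatment as well as in diabetes. Pooling cannot be told apart from the defect, because the 4 embryos labelled with a defect were measured alone and all other samples were pools. The labels do not say whether the diabetic pools held embryos with defects.

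The non-normalized table gives, per the file headers, an average signal intensity per probe and array, with its standard error over beads and its number of beads, which the authors deposited without background correction or scaling. The detection p-values in the same table, the probability that a probe's signal comes from the negative controls, were deposited by the authors beside each intensity. The standard errors and bead numbers, other columns deposited per the file headers, were used to describe the arrays alone. The series' value table holds linear intensities that the authors deposited after background subtraction and normalization by a method its labels do not state; its values reached down to -18.6, and its ranks within each array equalled those of the non-normalized table (Spearman's rho of 1 on 12 of 12 arrays). Column medians of the value table were 8.44 to 8.70. It was used as an alternative, with values under 1 set to 1 before taking log2.

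Intensities were processed with limma 3.58.1 in R 4.3.3. The function neqc subtracted the background by a normal-exponential model, with negative-control statistics inferred from the detection p-values, added an offset of 16, quantile-normalized the arrays and took log2. Of 32766 probes, 23340 had 1 gene symbol in the platform annotation, 13 had several and 9413 were not listed there. Symbols were updated through Entrez identifiers for 23267 of the 23353 annotated probes, and no gene was named from a probe with several symbols. A probe was kept with a detection p under 0.05 on at least 4 of 12 arrays, which left 13876 probes, 11247 of them with 1 gene name. The probe with the highest mean stood for each gene, giving 7341 genes, of which 2661 had more than 1 probe. Among the 58 further probes of 41 genes called between diabetic and control pools, 54 moved in the called direction (33 of them with unadjusted p under 0.05) and 4 in the opposite direction.

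Each comparison was fitted with limma's lmFit and eBayes on the 8 arrays of the groups compared, without covariates, two-sided, with Benjamini-Hochberg adjustment over 7341 genes and a threshold of 0.05. The design, 30 gene lists of pathways and cell types and the alternatives were set before the data were examined. Lists with at least 5 measured members, 27 of them, were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the 27 lists of a comparison; an estimated correlation and the rotation test fry were alternatives. Of the lists left untested, the ribosomal protein list had 0 members among the genes tested, the sex-linked list 1 and the placenta and decidua list 2, Hand1 and Cited1, with log2 differences of 0.06 and -0.02 between diabetic and control pools. Named genes followed a fixed rule: the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, all where fewer were called, the 5 with the smallest p per direction where none was called, and up to 4 members with the smallest p of each list described. Genes known by clone or locus names were counted without being named. The replication-dependent histone family, the S-phase, replacement-histone and forebrain and midbrain sets, the noncoding genes and the genes apart in single embryos were chosen after the values were seen.

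A probe undetected on every array of a group has only a bound there. Its fold was computed as the mean of the brighter group over the mean, in the dimmer group, of the higher of the probe's own value and the lowest value of a detected probe on each array, and is written as at least N-fold.

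The spread within a group was the root mean square distance over genes of each sample from the mean of the other samples of its group. Genes 2-fold from control were counted per sample against means of 3 control pools, leaving each control pool out in turn. Both were compared by exact two-sided permutation tests over 70 arrangements, for which the smallest possible p is 0.0286, with adjustment over 3 comparisons. The correlation of fold changes that share control pools was set beside 100 simulated draws of unchanged groups against the same pools and beside all 6 ordered divisions of the control pools into pairs. Called genes were set beside the same number of top genes by p in each such draw or division. In the draws for this check, each gene varied independently of the others.

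The procedure was tested on simulated data with 200 of 7341 genes changed, in 10 draws per comparison; this test was written after the first fit to the real values and led to no change of the fit. For diabetic against control pools it recovered 76% of changes of 1.41-fold and 98.6% of changes of 2-fold, and 4.95% of calls were false. For NTD embryos against control pools these shares were 62.8%, 95% and 4.19%, and for NTD embryos against diabetic pools 56.1%, 94.6% and 4.86%. The simulated values were normal, each gene varied independently of the others, and both groups had the same SD. In the real values genes can be correlated and the groups differed in spread, so these shares may not hold there. Alternatives covered the background correction, the scaling (median scaling, cyclic loess, the authors' value table), the detection filter, the choice of probe, the model (all 12 arrays in 1 fit, array weights, trended and robust variance, a replicate block, Kdm5d level as covariate), the threshold, the list test and leaving out each sample. Slides are not named in the labels or headers, so no batch was tested. The numbers of arrays limit the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.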

Results

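Gene expression was measured in whole NOD mouse embryos at embryonic day 10.5, shortly after the neural tube normally closes, in 12 samples of 3 groups. The control group held 4 pools of RNA from 4 embryos each, from normal pregnancies. The diabetic group held 4 pools of the same size from diabetic pregnancies. The third group held 4 individual embryos with neural tube defects, the NTD embryos, from diabetic pregnancies. The labels do not say whether the diabetic pools held embryos with defects, nor whether pools and NTD embryos shared litters. Between 12546 and 13736 of 32766 probes were detected per array (38.3 to 41.9%), with a median of 44 or 45 beads per probe and a median intensity of 55.3 to 62.2. Pearson correlations of log2 values across genes between samples of a group were 0.995 to 0.997 among control pools, 0.991 to 0.996 among diabetic pools and 0.984 to 0.992 among NTD embryos. The first principal component, with 27.2% of the variance, did not separate the groups: control pools lay at -3.91 to 5.38, within the -16.8 to 13.5 of the other samples. The second, with 20.1%, placed the control pools at 7.14 to 9.61 and all other samples at -13.2 to -0.16.

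The Y-linked demethylase gene Kdm5d, a marker of male tissue, had log2 values of 8.19 and 8.28 in control pools 1 and 2 and of 4.60 and 4.42, near background, in control pools 3 and 4. Its values were 7.23 to 8.97 in the diabetic pools, 9.18 and 9.05 in NTD embryos 1 and 2, and 4.59 and 4.48 in NTD embryos 3 and 4. Male tissue was thus unevenly distributed among the samples, and the counts of changed genes are also given without control pools 3 and 4.

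The first comparison asked whether embryos from diabetic pregnancies differ in expression from embryos of normal pregnancies. In the diabetic pools, transcripts of core histones were lower by the largest factors, together with Mir17hg, the host transcript of the miR-17-92 microRNA cluster, the chaperone gene Hspa1a and Erich5. Erich5 changed by a log2 fold change of -1.84 ± 0.12 (SE, n = 4 per group, limma adjusted p = 8.96e-06) and Mir17hg by -1.73 ± 0.12 (adjusted p = 1.31e-05). Hspa1a changed by -1.49 ± 0.11 (adjusted p = 1.30e-05), an inexact amount because it was detected in only 2 of 4 diabetic pools. Transcripts of Cln3, which encodes a lysosomal membrane protein, rose by 0.98 ± 0.08 (adjusted p = 4.65e-05). So did the immediate early genes Ier3 (0.86 ± 0.12), Egr1 (0.76 ± 0.12) and Ier2 (0.67 ± 0.10, inexact because it was detected in only 2 of 4 control pools). The 4 diabetic pools lay on the same side of the 4 control pools for each of these genes. This separation was a condition for naming them and adds no evidence.

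Among 7341 genes, 151 changed between diabetic and control pools at an adjusted p under 0.05 in limma, 62 higher and 89 lower. All 22 genes that changed at least 2-fold were lower. At an unadjusted p under 0.05, 1060 genes differed, against 367 by chance, and the groups did not overlap for 686 genes (9.34%, against 2.86% by chance). With median scaling in place of quantile scaling the split was 23 higher and 141 lower. The count was 42 without control pools 3 and 4, 58 without control pool 2, 64 without control pool 3, 81 without control pool 1, 84 without control pool 4, 77 without diabetic pool 1 and 91 without diabetic pool 3.

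Of the genes with the largest falls, 7 encode core histones. Among them were H2bc11 (-1.73 ± 0.12), H4c12 (-1.65 ± 0.10), H2bc6 (-1.61 ± 0.11), H2bc7 (-1.59 ± 0.12), H4c17 (-1.51 ± 0.14) and H4c18 (-1.50 ± 0.09), with limma adjusted p from 6.92e-06 to 7.22e-05. H2bc18 was undetected in all 4 diabetic pools and at least 2.59-fold lower (limma adjusted p = 8.96e-06), but its call was lost from the authors' value table (limma adjusted p = 0.0611). A further probe of H2bc6 fell by less (-0.53), while those of H4c12 and H4c18 fell by more (-1.73 each). Over the whole family of replication-dependent histone genes, examined because of these falls, 27 of 48 measured genes fell, 2 rose and 19 did not pass. The median log2 fold change was -0.65 over all 48 genes and -1.15 over the 27 that fell (2.22-fold lower). By class, 10 of 12 H2B, 10 of 11 H4, 4 of 9 H3, 1 of 13 H2A and 2 of 3 H1 genes fell. The genes that rose were H1f2 (0.44 ± 0.08) and H2bc4. The share that fell was 56.3%, against 0.850% of the other genes (Fisher's exact test, two-sided, p = 4.35e-41, a family chosen after its values were seen). Family members share sequence, so a probe can read several copies, and 13 of the 19 that did not pass lay above the 95th percentile of signal. Under 4 other settings of background correction or scaling, at least 24 of the 27 genes stayed called lower.

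Averaged over these 27 histone genes, the log2 difference from the control mean was -1.38, -1.13, -1.03 and -1.02 in diabetic pools 1 to 4, with a mean of -1.14 ± 0.17 (SD, n = 4), against an SD of 0.045 among control pools. It was -1.46, -1.13 and -1.40 in NTD embryos 1 to 3. In NTD embryo 4 it was -0.11.

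**Figure D1:**
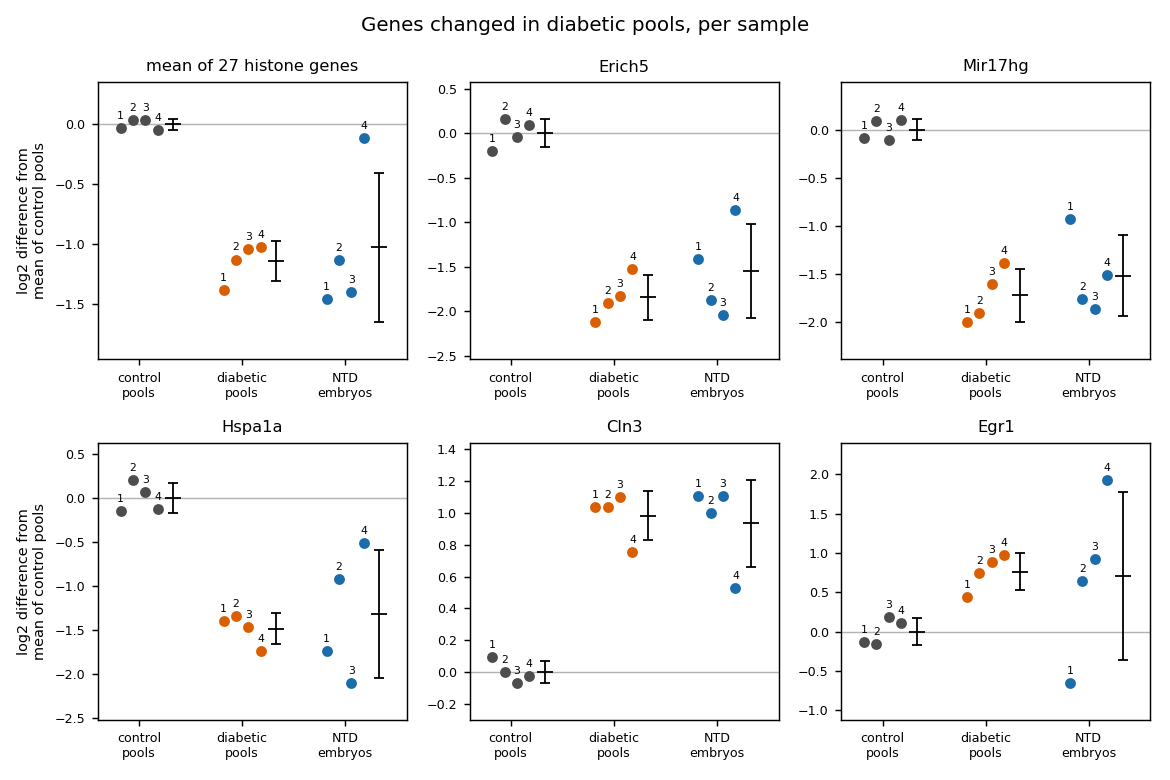
Log2 difference from the mean of the control pools for each sample (points, numbered by replicate) with the group mean and SD (bars), for the mean of 27 histone genes and for Erich5, Mir17hg, Hspa1a, Cln3 and Egr1. The histone mean was -1.38 to -1.02 in the diabetic pools and -0.11 in NTD embryo 4.

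Other large rises between diabetic and control pools were those of Mzt1, a component of the gamma-tubulin complex (0.69 ± 0.09, limma adjusted p = 0.00122), and of Msx3, a homeobox gene of the dorsal neural tube (0.58 ± 0.07, adjusted p = 9.26e-04). Dera, a deoxyribose phosphate aldolase gene, rose by 0.68 ± 0.13, the cytochrome P450 gene Cyp20a1 by 0.60 ± 0.14, Csf2ra, which encodes a subunit of a receptor for a granulocyte-macrophage growth factor, by 0.59 ± 0.12, and Rbfox3, which encodes a neuronal splicing factor, by 0.57 ± 0.11. The calls of these genes were less stable: of 21 alternatives, 10 ended the call of Dera, 16 that of Cyp20a1, 9 that of Csf2ra and 12 that of Rbfox3. For Dera the adjusted p was 0.0729, 0.0742 and 0.0790 without control pools 1, 2 and 3 and 0.0510 without diabetic pool 2. For Cyp20a1 it was 0.107 to 0.146 without any 1 of the control pools or without diabetic pool 1 or 3. For Csf2ra it was 0.0514 to 0.0862 without control pool 2, 3 or 4 or without diabetic pool 1 or 3, and for Rbfox3 0.0513 to 0.0836 without any 1 of the control pools or without diabetic pool 1, 2 or 3. With all 12 arrays in 1 fit, limma adjusted p was 0.551 for Egr1, 0.152 for Ier3, 0.222 for Mzt1 and 0.250 for Msx3. With array weights it was 0.207 for Egr1. Further probes of Msx3 (0.16 and 0.38), Cyp20a1 (0.29) and Rbfox3 (0.40) rose by less than the probes given above.

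Among the gene lists, the Hox genes, which pattern the body axis, were higher as a group in the diabetic pools. Of 30 measured Hox genes, 3 rose over all genes tested: Hoxb9 (0.45 ± 0.08), Hoxc9 (0.39 ± 0.09) and Hoxb4 (0.36 ± 0.07). Adjusted over the list alone, 13 rose and 1 fell. The median log2 fold change of the list was 0.25 and its mean 0.20 (camera adjusted p = 5.37e-07; adjusted p = 0.0260 with an estimated correlation; fry adjusted p = 0.00440). The list was called higher under all 4 other settings of background correction or scaling, with a mean of 0.13 under median scaling. The cholesterol synthesis genes were the other list called higher: of 11 measured members, 0 passed over all genes in limma (4 at an unadjusted p under 0.05) and 1, the mevalonate decarboxylase gene Mvd (0.37 ± 0.09), rose when adjusted over the list alone. That list's median was 0.24 (camera adjusted p = 0.00954), and the call was lost at an adjusted p = 0.162 with an estimated correlation, while fry gave an adjusted p of 0.00814.

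Several genes of lists that were not called changed as well between diabetic and control pools. Of 32 measured genes whose mutation causes neural tube defects in mice, 1 fell, Enah, which encodes an actin regulator (-0.65 ± 0.10, limma adjusted p = 0.00830), 0 rose and 31 did not pass (list median -0.0043, camera adjusted p = 0.949). Of 22 neuronal genes, the proneural factors Neurog2 (-0.44 ± 0.08) and Neurod4 (-0.40 ± 0.07) fell and 20 did not pass; the median of the list was 0.02, its mean -0.02 and its test downward (adjusted p = 0.872). Of 27 immediate early and heat shock genes, a list of handling stress, 4 rose, among them Ier3, Egr1 and Ier2, Hspa1a fell and 22 did not pass (median 0.05, adjusted p = 0.212). Of 22 genes of the endoplasmic reticulum and amino acid stress list, Herpud1 fell (-0.35 ± 0.07) and Atf3 rose (0.37 ± 0.08); the median was -0.08 (adjusted p = 0.124, fry adjusted p = 0.00440). The midbrain-hindbrain homeobox gene En2 rose (0.55 ± 0.10) among 17 brain-region genes, whose median was -0.0015, mean 0.09 and test upward (adjusted p = 0.351 over 27 lists). The Wnt receptor gene Fzd8 (-0.36 ± 0.07), the quinone reductase gene Nqo1 (-0.46 ± 0.09), the erythroid gene Hemgn (-0.44 ± 0.10) and the macrophage receptor gene Mrc1 (-0.47 ± 0.09) fell, each with an adjusted p from 0.0199 to 0.0477. The enolase gene Eno2 rose (0.52 ± 0.12, adjusted p = 0.0465) and the somite gene Meox1 rose (0.37 ± 0.08, adjusted p = 0.0333). Adjusted p of the 25 lists not called was 0.124 to 0.999.

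The second comparison set NTD embryos against control pools. These groups differ in the defect, in maternal diabetes, in pooling and possibly in gonadotropin, so no difference between them can be assigned to the defect. As in the diabetic pools, Cln3 rose (0.93 ± 0.12, SE, n = 4 per group; limma adjusted p = 0.0221) and Erich5 (-1.55 ± 0.22, adjusted p = 0.0302) and Mir17hg (-1.52 ± 0.18, adjusted p = 0.0142) fell. The histone gene H2bc4 rose (0.62 ± 0.08, adjusted p = 0.0196). Ccno, which encodes cyclin O, was undetected in the 4 NTD embryos and at least 1.43-fold lower (adjusted p = 0.0221), and Spats2 was likewise undetected and at least 1.33-fold lower (adjusted p = 0.0360). The remaining call, 6430411K18Rik, named here after its value was seen, fell by 1.04 (adjusted p = 1.28e-04).

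These 7 genes, 2 higher and 5 lower, were all that passed among 7341 in limma, while 752 differed at an unadjusted p under 0.05 and the groups did not overlap for 468 (6.38%, against 2.86% by chance). The count rested on single samples: it was 49 without NTD embryo 4, 30 without NTD embryo 1, 3 without control pool 1, and 1 without control pool 2, 3 or 4, without NTD embryo 3, or without both control pools 3 and 4. Of the 48 histone genes, 0 fell in limma with all 4 NTD embryos, although 30 were lower at an unadjusted p under 0.05, and 27 fell without NTD embryo 4. Median scaling shifted the median of all genes by -0.10 and called 1 gene higher and 18 lower, and the authors' value table called 0 higher and 1 lower. For the 6 named genes, the highest adjusted p was 0.0977 without control pool 1, 0.207 without control pool 2, 0.161 without control pool 3, 0.216 without control pool 4, 0.0882 without NTD embryo 2 and 0.0800 without NTD embryo 3.

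Of 27 lists, 7 were called between NTD embryos and control pools with the preset correlation, 4 higher and 3 lower, 0 with an estimated correlation and 1 by fry. Cardiac muscle genes had a median of 0.26 over 18 measured genes (camera adjusted p = 9.91e-08, and 0.451 with an estimated correlation). The mean of this list relative to control was 0.26, 0.48 and 0.30 in NTD embryos 2 to 4 but -0.0035 in NTD embryo 1. Adjusted over the list alone, 4 rose: the atrial myosin heavy chain gene Myh6 (0.54 ± 0.10), the natriuretic peptide gene Nppb (0.51 ± 0.12), Myl7 (0.39 ± 0.12) and Csrp3 (0.37 ± 0.11). Hox genes had a median of 0.21 over 30 genes (camera adjusted p = 9.91e-08, and 0.436 with an estimated correlation). Adjusted over the list alone, 7 rose, among them Hoxd12 (0.59 ± 0.13), Hoxc10 (0.50 ± 0.13) and Hoxa9 (0.37 ± 0.08). The mean of the Hox list relative to control was 0.16, 0.19 and 0.10 in NTD embryos 1 to 3 and 0.45 in NTD embryo 4. Cholesterol synthesis genes had a median of 0.18 (11 of 11 members above 0; adjusted p = 2.87e-05; adjusted p = 0.175 with an estimated correlation; fry adjusted p = 0.0346), and Idi1 (0.50 ± 0.13) and Dhcr7 (0.34 ± 0.11) rose adjusted over the list alone. Glycolysis genes had a median of 0.22 over 7 genes, with Aldoc (0.60 ± 0.19) and Aldoa (0.29 ± 0.09) rising adjusted over the list alone. The camera adjusted p was 0.0105, and 0.451 with an estimated correlation or 0.0532 without control pool 1. The mean of this list relative to control was 0.57 in NTD embryo 3 and 0.12 to 0.18 in the other NTD embryos. Over all genes, 0 members of these 4 lists passed in limma; at an unadjusted p under 0.05, 9 cardiac, 10 Hox, 4 cholesterol and 4 glycolysis genes were higher.

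The 3 lists called lower in NTD embryos against control pools were those of erythroid cells, neurons and the extracellular matrix. All 14 measured erythroid genes had negative values, with a median of -0.33 (camera adjusted p = 1.20e-05; adjusted p = 0.451 with an estimated correlation); the embryonic globin gene Hba-x had -0.32 ± 0.13 and the erythroid factor gene Klf1 -0.50 ± 0.21. Neuronal genes had a median of -0.21, with 19 of 22 below 0 (adjusted p = 3.48e-04; adjusted p = 0.451 with an estimated correlation); Dcx, which encodes a protein of migrating neurons, had -0.49 ± 0.19 and the motor neuron factor gene Isl1 -0.21 ± 0.10. Extracellular matrix genes had a median of -0.12, with 27 of 31 below 0 (adjusted p = 1.41e-04; adjusted p = 0.451 with an estimated correlation). Adjusted over the list alone, the collagen crosslinking gene Lox fell (-0.48 ± 0.10) and the collagen gene Col9a3 rose (0.44 ± 0.09), while for the erythroid and neuronal lists 0 members passed. Over all genes, 0 members of the 3 lists passed in limma; at an unadjusted p under 0.05, 4 erythroid, 3 neuronal and 8 extracellular matrix genes were lower. Each of the 7 lists kept its direction and its call under 4 other settings of background correction or scaling. The 32 neural tube closure genes had a median of -0.03 (adjusted p = 0.121), and Enah had -0.65 ± 0.20. The 20 lists not called had an adjusted p of 0.0761 to 0.977.

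**Figure D2:**
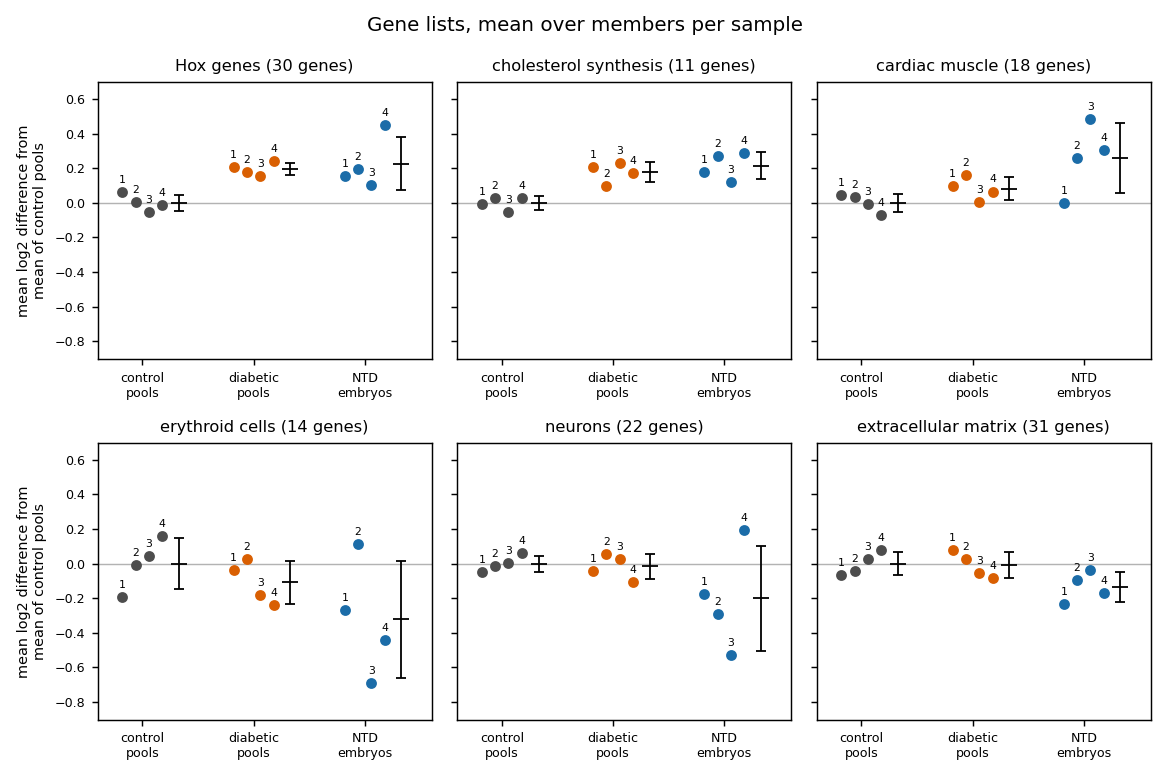
Mean log2 difference from the control mean over the measured members of 6 gene lists, for each sample (points, numbered by replicate), with the group mean and SD (bars). The erythroid mean was -0.69 in NTD embryo 3 and 0.12 in NTD embryo 2, and the neuronal mean -0.53 and -0.29 in the same embryos and 0.19 in NTD embryo 4.

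The third comparison set NTD embryos against diabetic pools, which share the maternal condition. No gene passed: limma called 0 of 7341 genes, with 224 at an unadjusted p under 0.05 against 367 by chance, and the groups did not overlap for 143 genes (1.95%, against 2.86% by chance). The smallest adjusted p was that of Ccno, undetected in the NTD embryos, at 0.215 (at least 1.41-fold lower, not passing). The muscle genes Mybphl (0.53 ± 0.09) and Fsd2 (0.43 ± 0.09), the ankyrin repeat gene Asb12 (at least 1.12-fold higher), the ciliary chaperonin gene Bbs12 (0.38 ± 0.09) and Ces1d (0.33 ± 0.08) had the next largest evidence above 0. The forkhead gene Foxq1 (-0.46 ± 0.11), the carboxylase gene Ggcx (-0.42 ± 0.09), Stard9 (-0.39 ± 0.10) and the collagen gene Col1a2 (-0.36 ± 0.09) were those below 0. None passed, with adjusted p from 0.491 to 0.996 for these 9 genes. The 2 further probes of Ggcx had -0.09 and 0.11 and did not bear out its direction.

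Of 27 lists, 4 were called between NTD embryos and diabetic pools with the preset correlation and 0 with an estimated correlation or by fry. Cardiac muscle genes had a median of 0.21 (camera adjusted p = 2.22e-07), and Nkx2-5, a cardiac homeobox gene (0.41 ± 0.11), and the alpha-actinin gene Actn2 (0.33 ± 0.10) rose adjusted over the list alone. Extracellular matrix genes had a median of -0.12 (adjusted p = 5.63e-06), with Col4a1 at -0.29 ± 0.11 and Col4a2 at -0.33 ± 0.13. Neuronal genes had a median of -0.20 (adjusted p = 1.73e-04), with Lhx5 at -0.45 ± 0.16 and Nefm at -0.44 ± 0.20, and erythroid genes a median of -0.23 (adjusted p = 1.91e-04), with Alas2 at -0.34 ± 0.21. Each of the 4 had an adjusted p = 0.596 with an estimated correlation. Without NTD embryo 3 the erythroid and neuronal lists lost their calls, at an adjusted p of 0.175 for each. Adjusted over the list alone, 0 members of the last 3 lists passed in limma; at an unadjusted p under 0.05, 6 extracellular matrix, 2 neuronal and 0 erythroid genes were lower. The Hox genes had a median of 0.02 between these groups (adjusted p = 0.295), and the 23 lists not called had an adjusted p of 0.0561 to 0.991.

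The title of the series speaks of individual risk, so the spread among samples of a group and the genes apart in each sample were compared. The distance of a sample from the rest of its group was 0.151 ± 0.012 on the log2 scale among control pools (mean ± SD, n = 4), 0.186 ± 0.031 among diabetic pools and 0.254 ± 0.039 among NTD embryos. After adjustment over the 3 comparisons, no difference passed: NTD embryos against control pools had an exact permutation p of 0.0286 (adjusted 0.0857), NTD embryos against diabetic pools 0.0571 (adjusted 0.0857) and diabetic against control pools 0.114 (adjusted 0.114). Leaving out single samples moved the unadjusted values: exact p was 0.0571 for NTD embryos against control pools without control pool 1 or 2, 0.0286 for NTD embryos against diabetic pools without NTD embryo 1, 2 or 3 but 0.229 without diabetic pool 1 or 3, and 0.0286 for diabetic against control pools without diabetic pool 1 or 3 but 0.4 without control pool 1 or 2. The median over genes of the ratio of variances was 2.58 for NTD embryos over control pools, 1.62 for NTD embryos over diabetic pools and 1.62 for diabetic over control pools. A pool of 4 embryos averages individual differences, so the NTD embryos, measured alone, were not compared on equal terms.

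A control pool had 1 or 2 genes that differed at least 2-fold from the mean of other control pools. Diabetic pools had 27.8, 25.5, 23 and 23.5 such genes, averaged over the choices of control pools, and NTD embryos had 35.5, 26.8, 60.8 and 60.3. A control pool was counted against its own group and every other sample against another group, so any shift of group means raises the counts of the others. NTD embryos were also measured alone and not as pools, which can raise their counts without an effect of the defect. With these limits, diabetic pools and NTD embryos both exceeded the control pools (exact permutation p = 0.0286 each, adjusted over 3 comparisons 0.0429), by a mean of 23.4 and 44.3 genes. Without the histone genes these excesses were 7.56 and 30.7, so that most of the genes counted in the diabetic pools were histone genes, and from the authors' value table they were 50.3 and 125 (exact p = 0.0286 each). The difference between NTD embryos and diabetic pools did not pass (exact p = 0.0571), and moved both ways when 1 sample was left out: exact p was 0.0286 without control pool 1, 2 or 4 or NTD embryo 2, 0.0857 without diabetic pool 1, 0.143 without diabetic pool 2 and 0.171 without diabetic pool 3 or 4. Of 35 genes 2-fold from control in any diabetic pool, 16 were lower in all 4 pools. Of 116 genes 2-fold from control in any NTD embryo, 0 were so in all 4, 20 in 3, 18 in 2 and 79 in 1 embryo, with 1 gene counted in both directions. Among the 79, 45 belonged to NTD embryo 4, 24 to NTD embryo 3, 9 to NTD embryo 1 and 1 to NTD embryo 2.

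**Figure D3:**
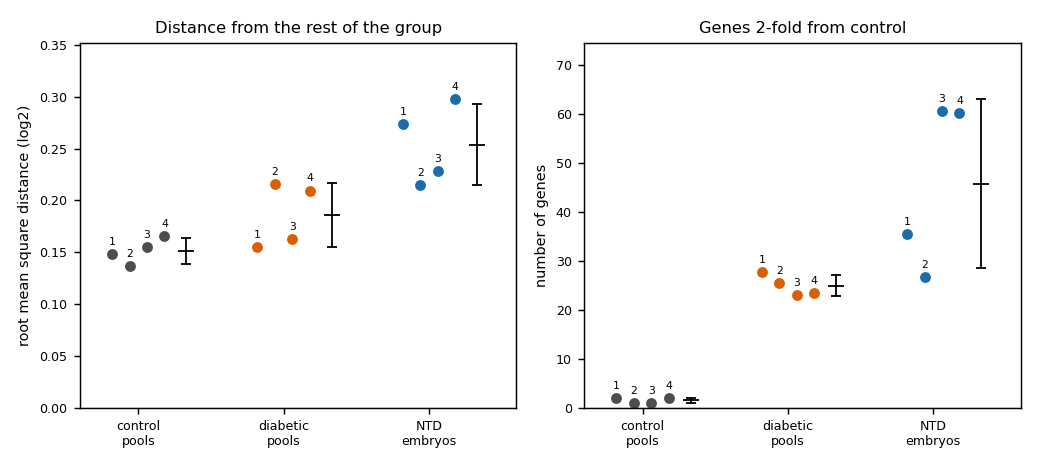
Root mean square distance of each sample from the mean of the rest of its group (log2, left) and number of genes at least 2-fold from control (right), with the group mean and SD (bars). NTD embryos 3 and 4 had 60.8 and 60.3 genes 2-fold from control, and NTD embryos 1 and 2 had 35.5 and 26.8.

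The changes of diabetic pools and of NTD embryos against control pools ran in the same direction. Over all genes, 71.1% had the same sign in both comparisons, against 61.6% when unchanged groups were simulated against the same control pools. All 151 genes called in the diabetic pools had the same sign in the NTD embryos. The 151 top genes of each simulated draw gave a mean of 117 and a highest value of 126, a check chosen after the values were seen. Genes varied independently in the draws of called genes, so correlated genes could give a wider range, and the highest draw is no firm limit. With the control pools divided between the comparisons, 138 to 149 of the 151 top genes had the same sign. The Pearson correlation of the fold changes across genes, which are not independent replicates, was 0.743, against a mean of 0.316 and a highest value of 0.410 in 100 simulated draws. The covariance was 0.0213 against 0.00426 simulated, a difference of 0.0171 that estimates the part not due to shared controls. With the control pools divided in that way, the correlation was 0.364 to 0.595 and the mean covariance 0.0170. Both calls of higher genes in NTD embryos, Cln3 and H2bc4, were also among the 62 of the diabetic pools, where independent lists would share 0.0169 genes. Lists of these sizes from simulated unchanged groups with the same control pools shared 0.2 genes on average and up to 2. With the control pools divided, 0 to 2 were shared. Since 2 is also the most that these lists can share, the highest draw cannot decide whether this overlap goes beyond shared controls. Of the 5 lower genes, 4 were among the 89, against 0.0606 for independent lists and at most 2 in the simulation.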

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

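The search for samples apart from their group was run after the named genes were known, and no explanation was tested in this part. In each group of 4 samples, the gap of the highest or lowest sample to its neighbour was set against the range of the group for the named genes, the example members of gene lists and the list means. Of 261 groups tested, 15 had a sample beyond the 95% critical value of Dixon's test; chance flags about 1 in 20 groups, which is 13.1 here, so the number of such samples was close to that of chance. Among genes named for their change, log2 values apart from the rest were those of Rbfox3 in control pool 1 (5.84), H2bc11 in diabetic pool 1 (8.43) and Ggcx in NTD embryo 2 (5.48). Among Hox genes, NTD embryo 4 was apart for Hoxb4 (9.65) and Hoxc9 (9.89), diabetic pool 2 for Hoxc9 (9.31) and control pool 3 for Hoxb1 (7.11). Control pool 1 was apart for the aldolase genes Aldoc (6.55) and Aldoa (12.5), and control pool 4 for the cholesterol synthesis gene Hsd17b7 (10.1). NTD embryo 1 was apart for the cardiac gene Myh6 (9.94) and the motor neuron factor gene Isl1 (10.7), NTD embryo 4 for the matrix protease gene Mmp14 (10.6) and diabetic pool 4 for the axonal gene Cntn2 (7.33). The mean of the glycolysis list, as a log2 difference from control, was apart in NTD embryo 3 (0.57).

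A signal was also present in probes that carry no gene name in the platform annotation and that the comparisons therefore left out. Of 2625 such probes that passed the detection filter, 40 changed between diabetic and control pools in limma at an adjusted p under 0.05, 14 higher and 26 lower, with log2 fold changes from -2.22 to 1.31. Their genes were not identified here.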

How the results depend on the processing

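For counts of called genes and lists, alternatives left out below were within 1.5 times of the planned count, and no result reversed; the alternatives without control pools 3 and 4 and without the histone genes were chosen after seeing the data. Against 151 genes between diabetic and control pools, 96 were called from the authors' value table, 36 with all 12 arrays in 1 fit, 93 with array weights, 42 without control pools 3 and 4, 267 at an adjusted p under 0.1 and 50 of at least 1.5-fold; the last 2 follow from the threshold. Against 7 genes between NTD embryos and control pools, 19 were called with median scaling, 1 from the value table, 2 without a filter, 4 with a stricter filter, 31 with all 12 arrays in 1 fit, 44 with array weights, 2 with the Kdm5d covariate and 1 without control pools 3 and 4. Between NTD embryos and diabetic pools, limma called 0 genes under every alternative run (224 at an unadjusted p under 0.05 in the planned fit). Lists called fell to 1, 0 and 0 in the 3 comparisons with an estimated correlation, and fry called 1 list between NTD embryos and control pools and 0 between NTD embryos and diabetic pools. Leaving out 1 sample gave 58 to 174, 1 to 49 and 0 genes, and 2 to 3, 6 to 10 and 3 to 6 lists. It gave spread differences of 0.0177 to 0.0605 (diabetic against control pools), 0.0856 to 0.137 (NTD embryos against control pools) and 0.0419 to 0.102 (NTD embryos against diabetic pools), where median scaling gave 0.0741 and the authors' values 0.106, each with an exact p of 0.0286. The excess of genes 2-fold from control depended on the processing. For diabetic over control pools (23.4) it was 50.3 from the authors' values, 13.9 without background correction, 14.4 with the stricter filter and 7.56 without the histone genes; for NTD embryos over control pools (44.3) it was 125, 24.4, 29.4 and 30.7, each with an exact p of 0.0286. For NTD embryos over diabetic pools (20.9) it was 74.5, 10.4 and 14.9 (exact p = 0.0571 each), 31.3 with median scaling (exact p = 0.114) and 23.1 without the histone genes (exact p = 0.0286). With 1 sample left out these excesses were 22.5 to 25.8, 39.3 to 50.7 and 15.9 to 27.2. The correlation of shared changes was 0.650 to 0.768 with 1 sample left out and 0.692 without the histone genes. The cause of these differences was not tested. Of the named genes that passed, 11 of 20 between diabetic and control pools and 0 of 6 between NTD embryos and control pools kept their call under each alternative run for them, 19 to 21 per gene, the block not counted. The replicate numbers were not taken to pair the samples, because not every pair correlated above 0.1 in any comparison: correlations of deviations between samples of the same number were -0.269 to 0.0755, 0.00922 to 0.296 and -0.198 to 0.265 in the 3 comparisons. In NTD embryos against control pools, pairs 1, 3 and 4 (0.202, 0.145 and 0.296) did correlate best with their own number and pair 2 did not; in the other comparisons no pair did. With the number as a replicate block, 57, 1 and 0 genes were called and the list counts stayed at 2, 7 and 4. The block ended the calls of all 6 named genes between NTD embryos and control pools (limma adjusted p from 0.0732 to 0.132) and, between diabetic and control pools, those of Cyp20a1 (0.0931), Csf2ra (0.0863) and Rbfox3 (0.0708). A block for the slide was not run, because slides are not named. About 40.8% of probes were above background on the median array, so that changes of transcripts near background were measured as bounds or missed.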

Other observations

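The sets, enrichments and single-embryo genes in this part were chosen after the values were seen, and so were the tests of the histone, Hox and spread patterns while the thresholds for the other splits of the samples were set after the gene and list counts were known and before the result of each split test was seen. Noncoding RNA genes were over-represented among the genes that fell in the diabetic pools. Of 124 measured genes that the reference annotation classes as long noncoding RNA, 11 fell and 3 rose (8.87% lower, against 1.08% of other genes; Fisher's exact test, two-sided, p = 2.48e-07, 1 class tested). Several host microRNAs: Mir17hg had a log2 fold change of -1.73 ± 0.12, Dnm3os, which hosts miR-199a and miR-214, -1.21 ± 0.10 and Mir99ahg, which hosts let-7c and miR-99a, -0.72 ± 0.09 (SE, n = 4 per group). Of the small nucleolar RNA host genes, Snhg12 (-0.40 ± 0.07) and Snhg16 (-0.35 ± 0.08) were among those that fell. Between 7 and 11 of the 11 genes stayed called lower under 4 other settings of background correction or scaling. In the NTD embryos, values of Dnm3os relative to the control mean were -0.17, -1.32, -1.53 and -1.79. Of other noncoding genes that fell in the diabetic pools, Dancr (0.52) and Rab26os (0.42) lay above the control mean in NTD embryo 1 and Dleu2 (0.14) in NTD embryo 2. They lay below it in the remaining embryos, and Mir17hg, Mir99ahg, Snhg12 and Snhg16 did so in all 4.

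Some genes were at least 2-fold from the control mean in 1 NTD embryo alone, and differed between embryos. In NTD embryo 4, the forebrain and thyroid homeobox gene Nkx2-1 was lower than the control mean by the largest amount (log2 difference -3.33). Its log2 value there, 4.79, lay at that of Spats2, which was undetected in the NTD embryos, so the amount is inexact. Fezf1, a forebrain transcription factor gene (-1.83), and the fast muscle gene Mylpf (-1.51) were also lower in this embryo, while Egr1 (1.93) and Fgfbp3 (1.68) were higher. In NTD embryo 3, the stress response gene Chac1 (1.64) and Ier3 (1.54) were higher and the gap junction gene Gjb2 (-1.60), C1qtnf3 (-1.48) and the pigment cell gene Dct (-1.44) were lower. The log2 value of Dct there, 5.09, was close to background, so its amount is inexact too. In NTD embryo 1, Fos (-2.17), the glucagon gene Gcg (-1.88) and Lmx1a, a gene of the roof plate (-1.06), were lower. The planar polarity gene Dvl2 was lower as well (-1.17). Its log2 value there, 4.95, lay under that of the undetected Spats2 (5.13), so this amount is inexact. In NTD embryo 2 the hypoxia and stress gene Ddit4 (1.15) was higher. Being the only embryo past 2-fold does not make a gene unchanged in the others: Ier3 was also above the control mean in NTD embryos 1, 2 and 4 (0.42, 0.95 and 0.25), and Dct lay below it and Ddit4 above it in all 4 embryos. These genes were not tested embryo by embryo. The SD of these genes among control pools ran from 0.048 to 0.544, the highest being that of Fos.

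Other splits of the samples were used to ask whether chance can be excluded. For diabetic against control pools, 1 of 35 splits, the real one, called as many as 151 genes, and the highest other split called 5. For NTD embryos against control pools, 1 of 35 splits, again the real one, called as many as 7 genes, and the highest other split called 1. A share of 1 in 35 is the smallest that these splits can give, and it was not adjusted for the number of comparisons. Chance is thus unlikely for each of these 2 counts taken alone, but it is not excluded. For NTD embryos against diabetic pools the real split called 0 genes and the highest other split 2; all 35 of 35 splits must reach 0, so the splits decide nothing there. For the number of lists called with the preset correlation, chance stays likely enough in every comparison that the splits give no evidence against it. As many as the 2 lists of diabetic against control pools were called in 16 of 35 splits. As many as the 7 of NTD embryos against control pools were called in 11, and as many as the 4 of NTD embryos against diabetic pools in 22. The highest other splits called 5, 10 and 10.

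The fall of replication-dependent histone transcripts in the diabetic pools and in NTD embryos 1 to 3 was weighed against several explanations. Of 41 other S-phase genes, the 22 measured had a median log2 fold change of 0.0065 ± 0.033, so they showed no general fall. Here and below, the value after ± is the SE of a median over genes. It treats genes as independent and can be too small. The median was -1.15 for the 27 histone genes called lower and -0.65 for all 48 measured. Whether other S-phase transcripts follow the share of cells in S phase as closely as histone transcripts was not tested. Fewer cells in S phase therefore stays open. Scaling is excluded as the whole cause, because at least 24 of 27 histone genes stayed lower under 4 other scalings. A lower yield of transcripts without a poly(A) tail would spare the 9 measured replacement histone genes, which make polyadenylated transcripts and had a median of 0.066 ± 0.047. It would be expected in all replication-dependent classes, yet 1 of 13 H2A and 4 of 9 H3 genes fell, against 10 of 12 H2B and 10 of 11 H4 genes. Of the 12 H2A genes that did not pass, 10 lay above the 95th percentile of signal, so the classes do not settle this. A lower yield stays open, as does an effect of maternal diabetes, or of gonadotropin if control dams went without it. Neither of these effects was tested. NTD embryo 4 had control-like histone values. On a scale from control pools at 0 to diabetic pools at 1, its median position was 0.13 over the histone genes. Over 122 other called genes it was 1.01 ± 0.10, an SE over the genes of 1 embryo. A mislabelled control is therefore unlikely, but genes of 1 embryo can vary together and this SE is no measure of replicate spread.

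Higher Hox genes in the diabetic pools could follow from a smaller share of head tissue, in which most Hox genes are silent. Under that explanation forebrain and midbrain genes would fall by about as much as the Hox genes rose, to -0.25. The median of 12 of them was -0.015 ± 0.092 (SE over genes). But they went both ways (SD 0.255), with Fezf2 (-0.33), Nkx2-1 (-0.29) and Fezf1 (-0.26) lower without passing and En2 higher (0.55). The bound of 2 SE set for this test was thus too narrow, and a smaller share of head tissue stays open. The list was called higher under 4 of 4 other settings of background correction or scaling. Camera compares a list with all other genes, so a shift common to an array cancels and these calls cannot test scaling. The list mean was 0.13 with median scaling and 0.19 with cyclic loess, against 0.20 in the planned fit. The rise thus kept its direction, while its size depended on the scaling. Among the splits, 1 of 35, the real one, gave as large a difference of the list mean (0.20, against 0.15 in the highest other split). A difference in developmental stage or in the dissection of the trunk, and an effect of maternal diabetes, were not tested and stay open.

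The difference in spread between NTD embryos and control pools, which did not pass after adjustment (exact p = 0.0286, adjusted 0.0857), was weighed against the pooling. Averaging 4 embryos in a pool can lower the biological variance by up to 4 times, so a ratio of variances between 1 and 4 needs no further explanation, and the median ratio over genes was 2.58. Pooling may therefore account for the difference and stays open, but it cannot act between diabetic and control pools, both of 4 embryos, where the ratio was 1.62. A spread tied to the defect was not tested, because no single embryo without a defect was measured.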
